A study of Mus musculus with 16 samples.

How the data were processed

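RNA was measured in resident peritoneal macrophages of wild-type and Ogr1-deficient mice on the C57BL/6 background, kept for 24 h at 2 pH values in medium with 10% serum. Per the labels' protocols, RNA was purified on columns with DNase treatment, and labelled cRNA from 6 µg of total RNA was hybridised to Affymetrix arrays. The groups come from the sample labels, which give 4 replicates for each of the 4 combinations of genotype and pH. The sample names give pH 7.7 and pH 6.7, while the treatment text gives 7.6 and 6.8; the cause of the difference is not given in the sources used here. The labels name no date or batch, so no batch could be tested.

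The deposited table holds 1 intensity per probe set and array on a linear scale, from 0.88 to 5510, made by the authors with RMA, a method of background correction, quantile normalization and summary, in R 2.15.2 per the submitters' processing notes. Log2 of the deposited intensity was taken here. All 16 columns of the table belong to a labelled sample, and 0 pairs of arrays held identical values. The table has 241576 probe sets at the level of exons, of which 213361 carry 1 gene symbol in the platform annotation, 5107 several and 23108 none listed. Genes were named from probe sets with 1 symbol only. Of 20893 symbols, 18496 were current in the reference gene table (assembly GRCm38.p6, used for names and neighbours only), 2354 were updated through its synonyms and 43 kept as in the annotation, which gave 20848 genes with a median of 8 probe sets each. The targeted gene is not analysed here, so the knockout labels could not be checked against its transcript.

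The design was written before the data were examined, for values expected on a log2 scale with few probe sets per gene. The rule of taking the probe set with the highest mean as the gene's value was kept as written, although the probe sets turned out to cover single exons, and the mean over all probe sets of a gene, planned as an alternative, is given beside it. Genes were tested if they lay above the array's median, the 50th percentile, on at least 4 arrays, which left 15770. Each gene was fitted with limma 3.58.1 (R 4.3.3) with a mean for each of the 4 groups over all 16 arrays, moderated variances (eBayes) and Benjamini-Hochberg adjustment within each of 5 comparisons. These are pH 6.7 minus pH 7.7 in WT and in KO, the difference of these changes (interaction), and KO minus WT at pH 7.7 and at pH 6.7. The threshold was an adjusted p under 0.05. Errors of log2 fold changes are standard errors from this fit, and errors of levels are SDs over the 4 arrays of a group. No detection call was used, so the distance of a probe set from background was not measured, and a level is set only against the median of its array. All tests were 2-sided.

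A total of 41 gene lists was fixed before the data were examined. They cover pH sensing and regulation, lysosomes and autophagy, inflammation, interferon, antigen presentation, alternative activation, phagocytosis and complement, cytoskeleton, adhesion and matrix, energy and lipid metabolism, stress responses, early genes, p53 and cell cycle, subsets of peritoneal macrophages, markers of other cell types, and genes near the Ogr1 locus. Of their 803 genes, 763 had a probe set and 717 were tested. Each list was tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 41 lists of a comparison, and again with the correlation estimated from the data. No list passed with the estimated correlation in any of the 5 comparisons.

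The rule for named genes, also fixed before the data were examined, took, after the targeted gene, the 8 largest increases and 8 largest decreases past the threshold. In comparisons of 2 groups the arrays of the groups had to be without overlap. Predicted genes, clone names and pseudogenes were left out. Up to 4 members with the smallest p were taken from each list described, and the 10 smallest p where no gene passed. Genes named outside this rule are said to have been chosen after their values were seen.

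The steps were tested on simulated data with 200 genes changed, 100 by 2-fold and 100 by 4-fold, around the means and spreads of the 15770 genes. With the brightest probe set the WT comparison recovered 46% of the 2-fold and 88% of the 4-fold changes, the KO comparison 43% and 86%, the interaction 20% and 60%, KO minus WT at pH 7.7 55% and 85%, and KO minus WT at pH 6.7 48% and 84%. Between 2.3% and 7% of the calls in these simulated data were false. The simulated genes varied independently of each other and no array was set apart, so this share does not cover correlated genes or outlying arrays. With all probe sets averaged, the WT comparison recovered 93% of the 2-fold changes and the interaction 80%.

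Alternatives planned before the data were examined were no filter and a stricter filter at the 75th percentile, centring each array, another quantile normalization, an intensity trend with robust variances, the mean of all probe sets, every probe set tested by itself, array weights, the replicate number as a block, fits of the compared groups alone, stricter thresholds, and leaving out each array in turn. The combination of the mean of all probe sets with the omission of the array of WT pH 7.7 replicate 2 was added after seeing the data. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9.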

Results

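The series measured transcripts in resident peritoneal macrophages, the phagocytes that live in the abdominal cavity, taken from wild-type mice (WT) and from mice lacking Ogr1 (KO). Ogr1 is a receptor on the cell surface that senses protons. The cells of each genotype were kept for 24 h at pH 7.7 or at pH 6.7, with 4 arrays for each of the 4 groups and 16 arrays in all. The treatment text of the labels gives the values as 7.6 and 6.8, and the sample names, used here, give 7.7 and 6.7. Each array gave the intensity of 241576 probe sets, most of which cover a part of a gene. The array medians lay between 8.14 and 8.61 on the linear scale. Of 20848 genes with a probe set of their own, 15770 were bright enough to test. A gene's value was that of its brightest probe set, and the mean over all of its probe sets is given beside it where these rules part. The number of arrays limits the precision. The labels do not say whether the 4 arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The array of WT pH 7.7 replicate 2 stood apart from the other 15, with a median Pearson correlation with the other arrays of 0.883, against 0.907 to 0.923 for the others.

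The comparison within WT asked which transcripts differ between acidic and alkaline medium in cells that have the receptor. Arg1, which encodes the arginase of alternatively activated macrophages, was higher at pH 6.7 by a log2 fold change of 4.89 ± 0.81 (SE, n = 4 arrays per group, adjusted p = 0.00962). Pdk4, the kinase that holds back pyruvate dehydrogenase, was higher by 3.65 ± 0.70 (adjusted p = 0.0213). The chemokine gene Ccl22 rose by a log2 fold change of 3.17 ± 0.54, the BAFF receptor gene Tnfrsf13c by 3.35 ± 0.60 and Tph1, an enzyme of serotonin synthesis, by 2.67 ± 0.55. The lipase gene Lipn was lower at pH 6.7 (log2 fold change −3.07 ± 0.40, adjusted p = 0.00177), as was Lss, the lanosterol synthase of the cholesterol pathway (−2.28). Of the surface receptor genes, Slamf8 was 3.48-fold lower and Clec5a had a log2 fold change of −1.92. With these, Asb4 (log2 fold change 2.54), Epb41l3 (2.49) and Ferd3l (2.49) completed the 8 largest increases, and Scimp (−1.93), Matk (−1.70), Aig1 (−1.69) and Kif5c (−1.67) the 8 largest decreases. With all probe sets averaged, Arg1 had a log2 fold change of 4.02 ± 0.38, Pdk4 of 3.18 ± 0.42, Lipn of −2.22 ± 0.21 and Slamf8 of −1.85 ± 0.19. The changes of Ccl22 (1.32), Tnfrsf13c (1.06), Tph1 (0.97), Asb4 (1.20), Epb41l3 (1.44), Ferd3l (1.23), Lss (−1.10), Matk (−0.86) and Aig1 (−0.79) were smaller by that rule, and that of Kif5c, −0.11 (adjusted p = 0.704), no longer passed. Kif5c was also lost in 14 of the 16 fits that left out 1 array and Ferd3l in 13 (adjusted p up to 0.133 and 0.116), and Tph1 in 7. With array weights Ferd3l (0.0735) and Tph1 (0.0501) did not pass, nor did they with the replicate number as a block (0.0528 and 0.0699), by which Scimp was lost too (0.0553). The distance of a probe set from background was not measured. For genes whose lower group reached below the median of an array (3.03 to 3.11 in log2), the log2 fold changes are differences of the deposited values and do not measure how many times the transcript changed. All 4 arrays of the lower group lay below it for Lipn, Asb4, Ferd3l and Tph1, 3 of 4 for Tnfrsf13c, 2 of 4 for Arg1, Pdk4, Ccl22 and Clec5a, and 1 of 4 for Lss, Scimp and Epb41l3.

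**Figure D1:**
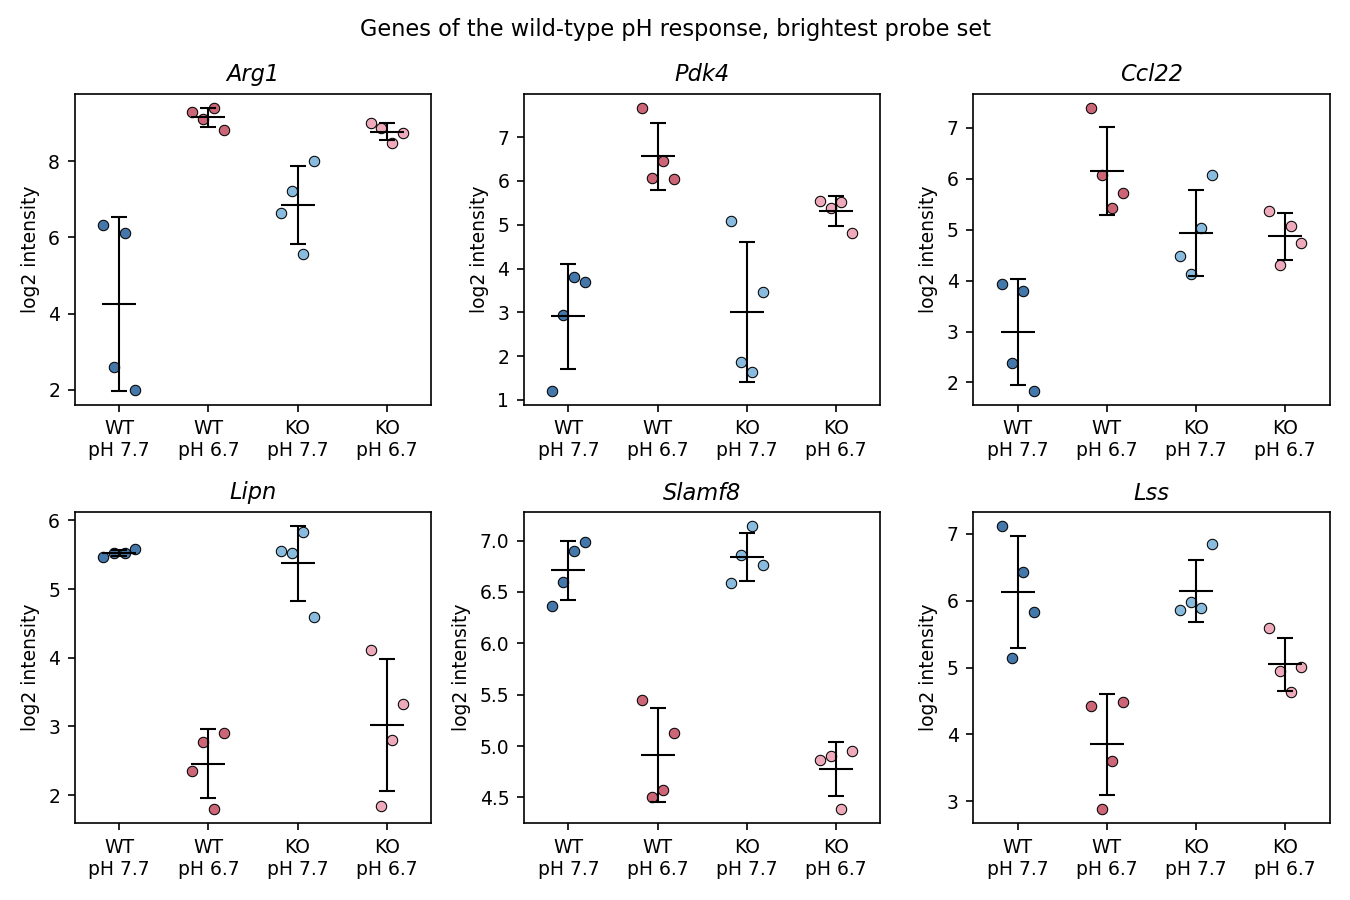
Log2 intensity of the brightest probe set of 6 genes on each of the 16 arrays (points, by genotype and pH), with the group mean and SD (bar and whiskers, n = 4). Arg1 lies between 8.80 and 9.39 on the 4 WT arrays at pH 6.7 and between 1.995 and 6.33 on the 4 at pH 7.7, while Lipn lies at 5.47 or above on the WT arrays at pH 7.7 and at 2.91 or below at pH 6.7.

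By gene group, cholesterol synthesis fell: of its 20 tested genes, 7 fell, 0 rose and 13 did not pass. When adjusted over the list alone, 13 fell. Sqle, the squalene epoxidase, had a log2 fold change of −1.47 ± 0.24, Hmgcs1, the enzyme ahead of mevalonate formation, −1.03 ± 0.19, and Cyp51 −1.52 ± 0.29. The median of the list was −0.78. The camera test, which compares the genes of a list with all others, gave it an adjusted p of 9.2e-18 over the 41 lists. With a correlation between the genes estimated from the data, its adjusted p was 0.124.

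Chaperones and folding enzymes of the endoplasmic reticulum shifted upward as a group, with a camera adjusted p of 5.3e-09, and of 0.124 with an estimated correlation. Of 19 genes 1 passed, Hyou1 (1.08 ± 0.23), and 11 were higher when adjusted over the list alone. Hyou1 was lost in 7 of the 16 fits without 1 array (adjusted p up to 0.098) and with the replicate number as a block (0.0824). The group of fatty acid use and lipid storage held 3 of 18 genes that rose, Pdk4, Angptl4, an inhibitor of lipoprotein lipase (2.38 ± 0.41), and Plin2, a coat protein of lipid droplets (0.82 ± 0.16). Adjusted over the list alone 9 were higher, and the camera adjusted p was 2.3e-05, or 0.124 with an estimated correlation. Of 11 genes of alternative activation, 3 rose, Arg1, the eosinophil-associated ribonuclease gene Ear2 (2.04 ± 0.37) and the receptor gene Il4ra (0.89 ± 0.20). Il4ra did not pass over all probe sets (0.45, adjusted p = 0.107), with array weights (0.0806), with the replicate number as a block (0.0753) or in 14 of the 16 fits that left out 1 array. Adjusted over the list alone 3 were higher, and the camera adjusted p was 1.2e-05, or 0.124 with an estimated correlation. Genes induced by low oxygen rose in 2 of 19 cases, the growth factor Vegfa (1.16 ± 0.13) and the lipid droplet protein Hilpda (1.94 ± 0.27, and 0.96 over all probe sets), and 4 were higher when adjusted over the list alone. Their camera adjusted p was 0.00615, and 0.207 with an estimated correlation. The markers of mast cells had a median log2 fold change of 0.47 in the same comparison (camera adjusted p = 0.153; 0.00238 with all probe sets averaged, and 0.865 with an estimated correlation), in the direction of the alternative activation list. With all probe sets averaged their mean rose by 0.58 (exact permutation p = 0.2). The means of small (0.33, exact p = 0.0286) and large peritoneal macrophages (0.39, 0.0857), dendritic cells (0.22, 0.0286) and B cells (0.31, 0.2) were higher too. Those of eosinophils (−0.04) and of T and NK cells (−0.02) were lower.

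Smaller shifts were seen in the genes of the integrated stress response (1 of 26 rose, Nupr1, 1.05 ± 0.22; 4 adjusted over the list alone; camera adjusted p = 0.00576, and 0.429 with an estimated correlation) and in lysosomal genes (1 of 29 rose, the membrane protein Scarb2, 1.17 ± 0.13, and 0.78 over all probe sets; 1 adjusted over the list alone; camera adjusted p = 0.00576, and 0.543 with an estimated correlation). The lysosomal list did not pass with all probe sets averaged (adjusted p = 0.12) or after another quantile normalization (0.0505), and the stress list had an adjusted p of 0.05 without WT pH 6.7 replicate 4. Nupr1 was lost in 8 of the 16 fits without 1 array and with the block (0.0557). No complement gene of 13 passed on its own by limma, also when adjusted over the list alone (4 had an unadjusted p under 0.05), and the list had a median log2 fold change of 0.37. Its camera adjusted p was 0.00784, or 0.708 with an estimated correlation. Without WT pH 7.7 replicate 2 the adjusted p of the complement list was 0.116, and without WT pH 6.7 replicate 1 it was 0.123. Chemokines had a camera adjusted p of 0.0376 with 1 of 23 genes past the threshold, Ccl22, and 2 adjusted over the list alone, and 0.708 with an estimated correlation. The list did not pass with all probe sets averaged (adjusted p = 0.0505) or with array weights (0.0683). Leaving out WT pH 7.7 replicate 2 or 4 gave this list an adjusted p of 0.103 or 0.125, and leaving out WT pH 6.7 replicate 1 or 2 gave 0.308 or 0.0697. Among acid-base transporters and carbonic anhydrases, 1 of 13 rose, the endosomal sodium-proton exchanger Slc9a9 (1.60 ± 0.31), and the list as a whole did not pass (camera adjusted p = 0.729). Of 18 inflammatory mediators 1 rose, Il1a (0.82 ± 0.17), which had an adjusted p of 0.0525 after another quantile normalization and 0.0695 with the block, and was lost in 10 of the 16 fits without 1 array.

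In all, 189 of the 15770 genes differed between pH 6.7 and pH 7.7 in WT, 118 higher and 71 lower at pH 6.7 (limma, adjusted p under 0.05). Averaging all probe sets gave 743, of which 500 were higher, and 138 genes passed in the same direction by both rules. Fitting the 8 WT arrays alone gave 22. The count was 79 without WT pH 6.7 replicate 1, 97 without replicate 2, 99 without replicate 3, 95 without WT pH 7.7 replicate 3 and 106 without replicate 4. Of the 40 genes past the threshold that the naming rule took here, 19 passed in each of the 16 fits that left out 1 array, among them Arg1, Ccl22, Lipn, Slamf8, Vegfa, Sqle and Scarb2, and the adjusted p of the others rose to at most 0.147. Of the 40, 35 also passed in the same direction over all probe sets.

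The comparison within KO asked the same question of cells without the receptor. Cholesterol synthesis fell here too: of 20 tested genes 9 fell, 0 rose and 11 did not pass. When adjusted over the list alone, 16 fell. Hmgcs1 had a log2 fold change of −1.23 ± 0.19 (n = 4 arrays per group, adjusted p = 0.00406), Sqle −1.45 ± 0.24, Hsd17b7 −1.33 ± 0.27 and Cyp51 −1.38 ± 0.29. The list median was −0.96 against −0.08 for all genes, with a camera adjusted p of 1e-10, or 0.409 with an estimated correlation. Targets of NRF2, the regulator of antioxidant genes, rose in 3 of 20 cases. These were the glutathione transferase gene Gsta3 (1.09 ± 0.21), the sulfiredoxin gene Srxn1 (0.66 ± 0.14) and Osgin1 (1.15 ± 0.28), and 10 were higher when adjusted over the list alone. Osgin1 had 0.68 over all probe sets, by which Srxn1 did not pass (0.21, adjusted p = 0.368). The camera adjusted p of this list was 1.8e-06, or 0.409 with an estimated correlation.

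Genes of fatty acid use and lipid storage rose in 4 of 18 cases, Acadl (0.93 ± 0.22) and Ech1 (0.80 ± 0.18) of fatty acid oxidation, Angptl4 (1.62 ± 0.41) and Plin2 (0.69 ± 0.16), of which Ech1 did not pass over all probe sets (0.40, adjusted p = 0.0731). The camera adjusted p was 0.000728, or 0.409 with an estimated correlation, and adjusted over the list alone 8 were higher and 2 lower. In the integrated stress response 2 of 26 rose, the transcription factor gene Ddit3 (1.40 ± 0.31) and Mthfd2 (1.59 ± 0.35), and in the endoplasmic reticulum list 1 of 19 rose, Dnajb9 (0.92 ± 0.21). Ddit3 had 0.93 over all probe sets, by which Mthfd2 did not pass (0.61, adjusted p = 0.139). Adjusted over the list alone, 4 genes of the stress list were higher and 1 lower, and 2 of the other were higher. Both lists had a camera adjusted p of 0.0235, and 0.61 and 0.611 with an estimated correlation. Without KO pH 6.7 replicate 2 both adjusted p rose to 0.0622, and without KO pH 7.7 replicate 4 they were 0.0984 and 0.0668. The stress list also had 0.0537 without KO pH 6.7 replicate 4 and 0.0512 after another quantile normalization. Of inflammatory mediators, Il1a rose (0.70 ± 0.17), Il12a (−1.83 ± 0.40) and Csf2 (−0.81 ± 0.21) fell and 15 did not pass. Il12a had −0.43 over all probe sets. Csf2 did not pass by that rule (−0.33, adjusted p = 0.0973), once each array was centred on its median (−0.70, adjusted p = 0.0854), after another quantile normalization (0.103), with an intensity trend (0.102) or with the block (0.0825). Of 13 acid-base genes the carbonic anhydrase gene Car13 fell by its brightest probe set (−0.94 ± 0.18) and did not pass over all probe sets (−0.14, adjusted p = 0.683). Of 14 targets of LXR, the sterol sensor, Scd2 fell (−1.17 ± 0.25). Arg1 had a log2 fold change of 1.92 with an adjusted p of 0.191 by its brightest probe set, and of 2.17 with an adjusted p of 0.0027 over all of its probe sets. The mesothelial and fibroblast markers had a median of −0.38 (camera adjusted p = 0.412; 0.0033 over all probe sets, and 0.195 with an estimated correlation). As means, these markers (−0.37, exact permutation p = 0.0571) and those of mast cells (−0.42, 0.0571) and of T and NK cells (−0.31, 0.0286) were lower. Over all probe sets each of these lists had an exact p of 0.0286, while dendritic cells (0.12) and neutrophils (0.04) were higher. By that rule dim genes in general fell. With all genes split by brightness into 5 groups, the median change was −0.072 and −0.116 in groups 1 and 2, the dimmest. It was 0.01, 0.097 and 0.074 in the brighter ones. How much of the list changes goes with brightness was not tested.

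The 8 largest increases of single genes in KO were C87436 (6.41 ± 0.91), Bpifb9b (6.27 ± 0.93), Bpifb9a (5.93 ± 0.80), Itih5 (5.70 ± 0.73), Zfp595 (4.94 ± 0.88), Prss48 (4.28 ± 0.57), Pfn4 (3.16 ± 0.51) and the cadherin gene Cdh2 (3.15 ± 0.62). Averaged over all probe sets, their changes lay between −0.37 for Cdh2 and 0.85 for Bpifb9b, and those of C87436, Bpifb9b, Zfp595 and Prss48 passed. The largest decreases were Psg29 (−2.52), Amn (−2.48), Lipn (−2.35), Fat1 (−2.32), Aspm (−2.31), Ntrk2 (−2.25), Trpm8 (−2.21) and Slc6a18 (−2.18). Of these 8, Lipn alone also passed over all probe sets (−1.40 ± 0.21, adjusted p = 0.00111). For Bpifb9a, Bpifb9b, Csf2 and the chemokine gene Cxcl10, all 4 arrays of the lower group lay below the median of their array, and for 15 other named genes 1 to 3 of 4 did, so these sizes describe the deposited values only.

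In all, 595 genes differed in KO, 205 higher and 390 lower at pH 6.7. Averaging all probe sets gave 1188, of which 767 were higher, and 216 genes passed in the same direction by both rules. Fitting the 8 KO arrays alone gave 265 and weighting the arrays by quality gave 969. The balance of directions moved with the scaling, since 34.5% of the calls were higher at pH 6.7 as deposited, 62.1% of 671 when each array was centred on its median (417 higher and 254 lower) and 55.8% of 609 after another quantile normalization. The median of all genes was −0.08 as deposited and 0.03 after centring. The count was 232 without KO pH 7.7 replicate 1, 325 without replicate 2 and 301 without replicate 3, and it was 320, 348, 259 and 261 without KO pH 6.7 replicates 1 to 4. Of the 50 genes past the threshold that the naming rule took here, 18 passed in each of the 16 fits without 1 array, among them Hmgcs1, Sqle, Gsta3 and Lipn. Csf2 was lost in 13 of these 16 fits, and Angptl4, Aspm, Il1a, Osgin1 and Trpm8 in 7 each. With the replicate number as a block Angptl4 (0.0603), Aspm (0.0622), Il1a (0.0645) and Trpm8 (0.073) did not pass, and Aspm had 0.0545 after another quantile normalization. Of the 50, 24 also passed in the same direction over all probe sets.

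**Figure D2:**
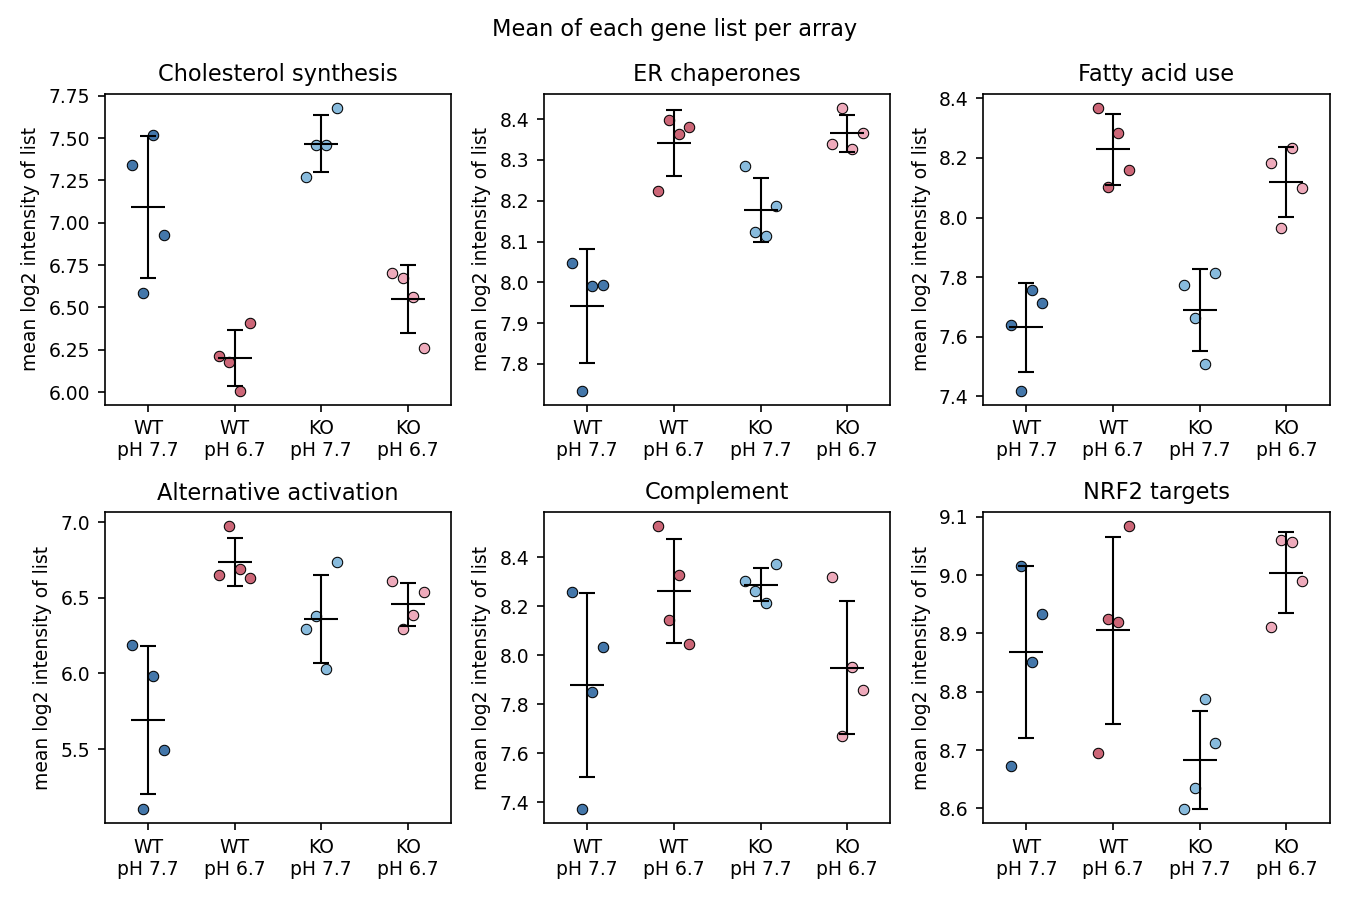
Mean log2 intensity of 6 gene lists on each array (points), with group mean and SD (n = 4), for WT and KO cells at pH 7.7 and pH 6.7. Cholesterol synthesis goes from 7.10 ± 0.42 at pH 7.7 to 6.20 ± 0.16 at pH 6.7 in WT and from 7.47 ± 0.17 to 6.55 ± 0.20 in KO, and alternative activation from 5.69 ± 0.49 to 6.74 ± 0.16 in WT and from 6.36 ± 0.29 to 6.46 ± 0.14 in KO.

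Set side by side, the WT and KO responses shared 53 genes, 29 higher and 24 lower at pH 6.7 in both. Independent lists of these sizes would share 1.53 and 1.76, and 0 of the genes called by limma in both responses went in opposite directions. Of the 731 genes called in at least 1 response, 453 (62%) changed in the same direction in both. No difference between the genotypes in the fall of cholesterol synthesis was detected by the test of the difference (median 0.01, camera adjusted p = 0.779). The comparisons use different arrays. Across all 15770 genes, which are not independent replicates, the changes had a Pearson correlation of 0.061 and a Spearman correlation of 0.085. With all probe sets averaged these were 0.326 and 0.271. By that rule 293 genes were called in both, 208 of them higher and 81 lower in both (24.32 and 6.49 for independent lists), and 4 went in opposite directions. Of the 1638 called in at least 1 response by that rule, 1303 (79.5%) changed in the same direction.

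**Figure D3:**
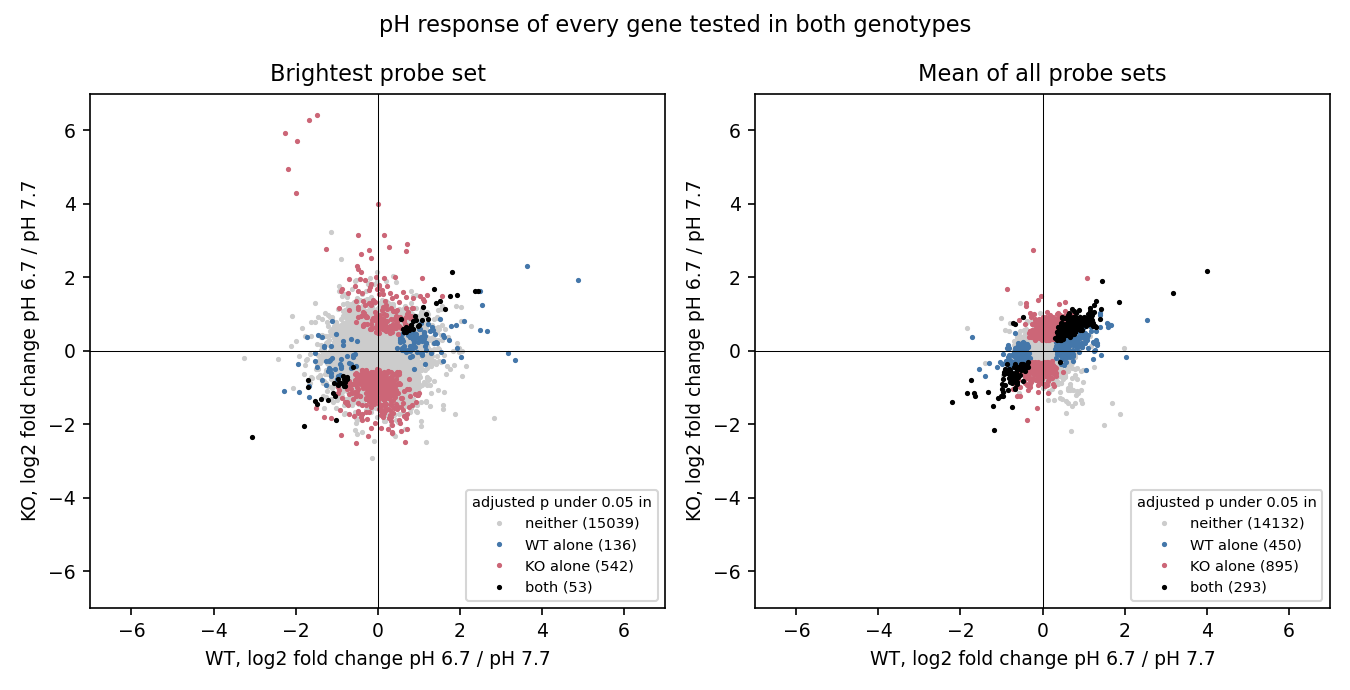
Log2 fold change between pH 6.7 and pH 7.7 in KO (vertical axis) against that in WT (horizontal axis) for 15770 genes (points), by the brightest probe set (left) and the mean of all probe sets (right), with the genes past the threshold in WT, KO, both or neither marked by colour. The 53 genes past the threshold in both by the brightest probe set lie in the lower left and upper right quadrants of the plot, 29 of them in the upper right.

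The difference between the KO and the WT response, the interaction, asked which changes with pH depend on the receptor. The largest positive differences were those of Bpifb9a (8.18 ± 1.14, adjusted p = 0.00887) and Bpifb9b (7.93 ± 1.31), a pair of neighbouring secretory protein genes, followed by C87436 (7.88), Itih5 (7.68), Zfp595 (7.13), the serine protease gene Prss48 (6.28), Zfp37 (4.03) and Cylc2 (3.02). The largest negative differences were those of Amn (−3.14 ± 0.57), Unc5cl (−2.85), the transporter gene Slc6a18 (−2.74), Fhdc1 (−2.57), the BMP receptor gene Acvr1 (−2.51), Grb10 (−2.49), Slc24a4 (−2.43) and Pbk (−2.34). All 4 arrays of at least 1 group lay below the median of their array for 5 of these 16 genes (Bpifb9a and Bpifb9b in KO at pH 7.7, Cylc2, Grb10 and Pbk), and some arrays of a group did for 9 others. For these the values, and the order of the genes by size, are those of the deposited intensities only. Of the 16, Zfp595 alone also passed over all probe sets (1.46 ± 0.25, adjusted p = 0.0324), and the value of Acvr1 turned to 0.01. Fhdc1 did not pass once arrays were centred (adjusted p = 0.0675), after another quantile normalization (0.0749), with the block (0.0697) or in 15 of the 16 fits without 1 array. Grb10 did not pass with the block (0.0644) or after another quantile normalization (0.051). Of the 19 genes past the threshold that the naming rule took here, 11 passed in each of those fits, among them Bpifb9a, Itih5, Acvr1 and Pbk, and the adjusted p of the others rose to at most 0.0896.

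Among the gene lists, alternative activation responded less in KO than in WT (median −0.66, camera adjusted p = 0.0153, and 0.717 with an estimated correlation), with 0 of its 11 genes past the threshold by limma, 4 at an unadjusted p under 0.05 and 1 lower when adjusted over the list alone. Complement genes had a negative difference (median −0.60, camera adjusted p = 0.00402, and 0.835 with an estimated correlation): their mean changed by 0.38 in WT and by −0.34 in KO, each with an exact permutation p of 0.114. By limma 0 of 13 passed in the difference, also when adjusted over the list alone, with 6 at an unadjusted p under 0.05. Markers of mast cells also had a negative difference (0.68 in WT and −0.42 in KO, as means), with a median of −1.16 over 10 genes (camera adjusted p = 0.153; 0.00017 over all probe sets, and 0.46 with an estimated correlation). Their mean was uneven over the WT arrays at pH 6.7, with an SD of 0.82 against 0.17 to 0.25 in the other groups. The exact permutation p was 0.2 for the change in WT, 0.0571 in KO and 0.0118 for the difference. By camera over all probe sets the markers of B cells (adjusted p = 0.00638), mesothelial cells and fibroblasts (0.0107) and small peritoneal macrophages (0.0386) had negative differences too. Each had 0.46 with an estimated correlation, and none of the 3 passed by the brightest probe set. Their mean differences over all probe sets were −0.46, −0.247 and −0.398. With all genes split by brightness into 5 groups of 3154, the median difference was −0.058 and −0.117 in groups 1 and 2, the dimmest. It was 0.004, 0.06 and 0.025 in the brighter ones. The camera test made no allowance for brightness, and how much of these list values goes with it was not tested. The alternative activation list had an adjusted p of 0.0751 without WT pH 7.7 replicate 2 and of 0.0999 without KO pH 7.7 replicate 4. NRF2 targets responded more in KO (median 0.32, camera adjusted p = 0.00402, and 0.717 with an estimated correlation), with 1 of 20 past the threshold, Srxn1 (1.02 ± 0.20), also when adjusted over the list alone. Of 29 lysosomal genes Scarb2 responded less in KO (−0.95 ± 0.19) and 28 did not pass. Srxn1 had 0.39 and Scarb2 −0.16 over all probe sets, neither of which passed, and Scarb2 had an adjusted p of 0.0778 once arrays were centred and 0.0787 after another quantile normalization. With the block Srxn1 had 0.0771 and Scarb2 0.0742. They did not pass in 12 and 11 of the 16 fits without 1 array.

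In all, 95 genes had a different response, 31 with a positive and 64 with a negative difference (limma, adjusted p under 0.05). The share of positive differences, 32.6%, became 54.2% of 72 with centred arrays and 54.9% of 71 after another quantile normalization. Over all probe sets of a gene the count was 11, 9 of them positive, and 6 genes passed in the same direction by both rules. The other probe sets of the called genes moved by a median of 0.05 in the direction of the brightest one (interquartile range −0.136 to 0.245), against 1.77 for the brightest one itself. For those above the median of the array on at least 4 arrays the median was 0.12 (−0.135 to 0.438), against 1.79. In the WT response the medians were 0.65 for all others against 1.05, and 0.73 for those above the median against 1.04. The KO response gave 0.17 against 0.997 and 0.265 against 0.965 in the same order, and KO minus WT at pH 6.7 gave −0.01 against 1.42 and −0.03 against 1.42, with 34 of 71 genes in the direction of the brightest one over all others. The count was 59 and 60 without WT pH 7.7 replicates 1 and 3, 56 and 52 without WT pH 6.7 replicates 2 and 4, 55 and 63 without KO pH 7.7 replicates 1 and 3, and 51 without KO pH 6.7 replicate 4.

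**Figure D4:**
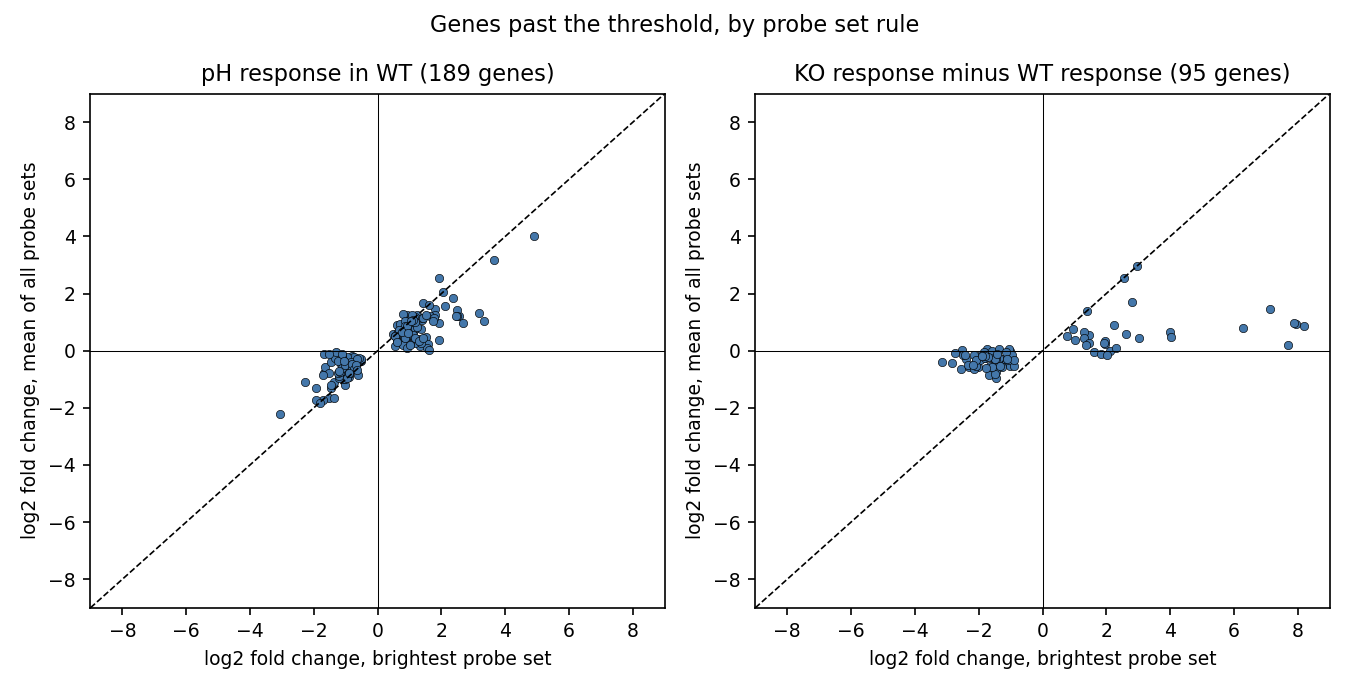
Log2 fold change over all probe sets of a gene (vertical axis) against that of its brightest probe set (horizontal axis) for the 189 genes past the threshold in the WT pH response (left) and the 95 past it in the difference between the KO and WT responses (right), with the line of equality dashed. For the 8 genes with the largest positive differences on the right, values between 3.02 and 8.18 by the brightest probe set meet values between 0.21 and 1.46 over all probe sets.

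At pH 7.7 the comparison of KO with WT gave the genotype difference in alkaline medium. No gene passed by limma, while 1703 of the 15770 genes had an unadjusted p under 0.05. The other splits of these 8 arrays into 4 and 4 gave a median of 898.5 such genes and at most 1497. The smallest adjusted p, 0.0731, was that of Zfp37 (−2.86 ± 0.43, lower in KO) and of the Fc receptor-like gene Fcrl1 (1.10 ± 0.17). Next came Rbm24 (1.17), Arl14epl (1.29), Gper1 (1.29), the mitochondrial transporter gene Abcb8 (−1.17), Itih5 (−3.81), Ern2 (1.12), Rprm (1.59) and Sec61a1 (0.65), with adjusted p between 0.0896 and 0.167. Over all probe sets the KO and WT arrays overlapped for Itih5 (2.08 to 2.30 against 2.11 to 2.69), Zfp37, Abcb8, Ern2, Fcrl1, Rbm24 and Arl14epl. They did not for Gper1, Rprm and Sec61a1. By the brightest probe set Itih5 lay below the array median on 3 of 4 KO arrays and Zfp37 on 1. Rprm did so on all 4 WT arrays and Arl14epl on some. The sizes of these changes describe the deposited values only. Over all probe sets 0 genes passed and 1274 had an unadjusted p under 0.05, against a median of 925.5 and at most 1425 in the other splits. A fit with an intensity trend and robust variances called 17 genes, among them Zfp37, Fcrl1, Rbm24, Itih5 and Sec61a1, and a stricter filter on brightness 3. With the block Arl14epl passed (adjusted p = 0.0471). Leaving out arrays, 10 genes were called without KO pH 7.7 replicate 4, 2 without WT pH 6.7 replicate 4 and 1 without WT pH 7.7 replicate 2 or 4.

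As groups, cholesterol synthesis (median 0.44), endoplasmic reticulum chaperones (0.30), alternative activation (0.39), complement (0.35), LXR targets (0.26) and chemokines (0.38) were higher in KO at pH 7.7 and NRF2 targets (−0.14) lower, with camera adjusted p of 0.00198, 0.00198, 0.0137, 0.0178, 0.0177, 0.0291 and 0.00198. With an estimated correlation the adjusted p of each was 0.464 or 0.694. By limma 0 genes of these lists passed, with 4, 6, 3, 0, 6, 7 and 6 at an unadjusted p under 0.05 in that order, and adjusted over the list alone 3 genes of alternative activation were higher and 2 NRF2 targets lower. Without WT pH 7.7 replicate 2, the array that stood apart, none of the 7 lists passed, and their adjusted p in the order above were 0.147, 0.0803, 0.118, 0.245, 0.118, 0.118 and 0.0803. Leaving out KO pH 7.7 replicate 4 gave cholesterol synthesis 0.0825, alternative activation 0.117, complement 0.0825 and chemokines 0.169. Complement had 0.0676 without WT pH 7.7 replicate 3, and LXR targets 0.069 and chemokines 0.13 without replicate 4. Over all probe sets the endoplasmic reticulum list (0.161) and LXR targets (0.118) did not pass. Several lists of cell markers lay higher in KO in the same comparison. This is not particular to them. By the mean of the brightest probe sets the lists of other kinds were higher too, except adhesion, NF-kB targets, interferon, cell cycle and NRF2 targets. The median of all genes was 0.076 as deposited and −0.002 with centred arrays, and the exact p of a list mean makes no allowance for this. The mean of the list of large peritoneal macrophages was higher by 0.32 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). That of small ones was higher by 0.41 (exact p = 0.171) and that of mast cells by 0.55 (exact p = 0.0571). Their camera adjusted p were 0.0929, 0.121 and 0.515. With all probe sets averaged these were 0.0154, 0.00587 and 0.0039, each with 0.508 with an estimated correlation, and the means were higher by 0.28, 0.34 and 0.49 (exact p = 0.0286 each). By the brightest probe set the neutrophil (−0.06) and eosinophil (−0.21) lists were lower in KO and the other marker lists higher. On WT pH 7.7 replicate 2 the small macrophage and mast cell lists had −0.435 and −0.432 against the other WT pH 7.7 arrays (all probe sets averaged). The marker lists were not tested without that array.

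At pH 6.7 KO and WT differed in 72 genes by their brightest probe sets, 19 higher and 53 lower in KO. Gbp9, a guanylate-binding protein gene of the interferon response, was lower in KO (log2 fold change −2.22 ± 0.23, n = 4 arrays per group, adjusted p = 0.000901), and Rad9b (−1.97 ± 0.22), Unc5cl (−2.23), Amn (−2.08), Smim1 (−2.01), the lipid enzyme gene Lpcat4 (−1.85), Cpne9 (−1.76) and Ccdc65 (−1.71) were also lower. Bpifb9b (4.98 ± 0.93), Bpifb9a (4.70), Itih5 (3.87), Prss48 (3.82), Cylc2 (2.33), the myosin gene Myh8 (1.60), Onecut2 (1.54) and the NADPH oxidase gene Nox3 (1.495) were higher in KO. None of these 16 passed over all probe sets, where Gbp9 had −0.52 (adjusted p = 0.383) and Itih5 turned to −0.03. All 4 arrays of the lower group lay below the median of their array for Cylc2, Nox3 and Smim1, 3 for Unc5cl, 2 for Bpifb9a, Bpifb9b, Prss48 and Lpcat4, and 1 for Itih5, Amn and Ccdc65, so these values too are differences of the deposited intensities. Gbp9, Rad9b and Onecut2 passed in each of the 16 fits without 1 array, and the adjusted p of the others rose to at most 0.136 when 1 was left out. Nox3 was lost in 13 of these fits, Amn in 9, Cpne9 in 8 and Bpifb9b and Itih5 in 7. With the block Nox3 (0.0762), Cpne9 (0.0563), Amn (0.054), Ccdc65 (0.0532) and Itih5 (0.0526) did not pass, and Nox3 had 0.0593 with an intensity trend. Cholesterol synthesis was higher in KO as a list (median 0.38, camera adjusted p = 0.000291, and 0.936 with an estimated correlation), with 0 of 20 genes past the threshold by limma, also when adjusted over the list alone, and 5 at an unadjusted p under 0.05. Over all probe sets the markers of mast cells (camera adjusted p = 0.0048), B cells (0.013) and mesothelial cells and fibroblasts (0.0236) were lower in KO as lists, each with 0.671 with an estimated correlation, while by the brightest probe set they had 0.155, 0.823 and 0.723. Dim genes in general were lower in KO by that rule over all probe sets. With all genes split by brightness into 5 groups, the median was −0.039 and −0.076 in groups 1 and 2, the dimmest. It was 0.022, 0.078 and 0.054 in the brighter ones.

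Over all probe sets 4 genes differed at pH 6.7, named here after their values were seen: Gm6983 (0.79 ± 0.11), which alone passed by both rules, Zfp595 (1.16 ± 0.18), 1700094D03Rik (0.86 ± 0.14) and Sh2d5 (−0.52 ± 0.08). The 8 arrays at pH 6.7 fitted alone gave 0, and array weights gave 116, while 1765 genes had an unadjusted p under 0.05 by the brightest probe set. The count was 43, 31, 39 and 39 without KO pH 6.7 replicates 1 to 4, and 41, 25 and 12 without WT pH 6.7 replicates 1, 2 and 4.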

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

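The tests of the other probe sets of a gene, of a mislabelled array, of the range of intensities on WT pH 7.7 replicate 2, of the counts without that array and of the splits by unadjusted p were chosen only after the result was seen; the others were set before.

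The genes whose pH response differed between KO and WT by the test of the difference were Bpifb9a (8.18), Bpifb9b (7.93), C87436 (7.88), Itih5 (7.68), Zfp595 (7.13), Prss48 (6.28), Zfp37 (4.03), Cylc2 (3.02), Amn (−3.14), Unc5cl (−2.85), Slc6a18 (−2.74), Fhdc1 (−2.57), Acvr1 (−2.51), Grb10 (−2.49), Slc24a4 (−2.43) and Pbk (−2.34), each as the log2 fold change in KO minus that in WT by its brightest probe set. Over the 8 genes with positive differences, the deviations of the arrays from their group means correlated between genes with a median r of 0.568 (28 pairs, from 0.136 to 0.912).

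For these calls, the tables argue against a chance assignment of arrays and against a single array as the source: 1 of 100 draws that exchanged genotype labels within each pH, the real one, gave 95 genes, the highest other gave 2, and the lowest count without 1 array was 51. The 11 calls over all probe sets were reached in 1 of 100 draws, with a highest other count of 1. What the tables leave open is a change of single probe sets, since the other probe sets of the called genes moved by 3% of the change of the brightest one, and those above the array median on at least 4 arrays by 6.7%. This is not particular to the interaction: the same shares were −0.5% and −2.3% for the calls between KO and WT at pH 6.7 and 17.1% and 27.4% for those of the KO response, against 62.4% and 70.6% in the WT response, so calls at pH 6.7 and in the KO response are open to the same doubt. The interaction values are consistent with calls that rest on an exon, on cross-hybridisation to another transcript or on faults of single probe sets, which were not tested apart, and a dependence of some exons on the receptor stays open as a biological explanation that was not tested.

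The array of WT pH 7.7 replicate 2 had the lowest correlation with the others. A mislabelled array of cells kept at pH 6.7 is argued against, since on a scale from 0 (the other WT pH 7.7 arrays) to 1 (WT pH 6.7) it lay at −0.296. It had the narrowest distance from its median to its 75th percentile, rank 1 of 16 (1.94 against 1.97 for the next and 2.08 for the widest), in line with a technical difference of that array. RNA of other cells cannot be told apart from this: the highest difference of a marker list was 0.939 (log2, all probe sets averaged, against the mean of the other 3 WT pH 7.7 arrays), for eosinophils, and it came mostly from 1 gene, Ear6 (1.604, and 0.043 by its brightest probe set), since the other tested marker, Epx, had 0.274 and the untested Prg2, Ccr3 and Il5ra 0.202, 0.173 and 0.088 (genes named after their values were seen). So it says little about eosinophils, while the B cell list was higher by 0.239, and the mast cell and small peritoneal macrophage lists had −0.432 and −0.435. The B cell list lay above each of the other 3 arrays (SD 0.069). Its largest differences were Cd79b (0.767) and Cd79a (0.649), with 0.622 and 0.68 by the brightest probe set. Pou2af1 (0.564) and Blk (0.558) had −0.314 and −0.813 by that rule, and Cd22 (−0.245) and Cd5 (−0.275) were lower (genes named after their values were seen). The labels name no sorting of the cells, and a difference between animals was not tested.

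The KO response held 3.15 times as many calls as the WT response (1.6 times over all probe sets). The array of WT pH 7.7 replicate 2 is argued against as the whole source: with it and 1 of the KO pH 7.7 arrays left out, so that each genotype lost 1 array, the median ratio was 3.23 (4 fits, from 2.71 to 6.64; 1.94 to 7.3 in the 12 such fits without another WT pH 7.7 array). A wider range of intensities on the KO pH 6.7 arrays is argued against too, since after another quantile normalization the ratio was 2.94. A larger response in KO cells stays open: over 560 genes called for the average effect of pH, the mean change was 0.717 in WT and 0.815 in KO, with an exact permutation p of 0.0882 over 4900 assignments (2-sided), and over all probe sets the changes were 0.424 and 0.445 (p = 0.581, exact). These genes were picked in the same data by the average of both responses, which favours genes that change alike. Only 53 genes were called in both responses, so the score says little about genes called in KO alone. The spread within groups was 0.469 and 0.501 for the WT groups and 0.437 and 0.483 for the KO groups (typical SD, log2), and no test set it against the counts.

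A chance assignment of arrays is argued against for the count of 189 in the WT response (1 of 35 splits as large, highest other 2). The same holds for 595 in the KO response and 72 between KO and WT at pH 6.7 (each 1 of 35, highest other 1). The 1 split is the real one, and 1 of 35 (2.9%) is the smallest share that these splits can give. For KO against WT at pH 7.7 the count was 0, which all 35 splits reach whatever the data (highest other 1), so it decides nothing about chance. At an unadjusted p under 0.05, no other split reached the 1703 genes by the brightest probe set (1 of 35 as large, highest other 1497). Over all probe sets 4 of 35 splits gave 1274 genes or more (highest other 1425), so chance stays open for this comparison.

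A sample far from the other 3 of its group, with a gap over the group's range above 0.829, was found in 14 of 236 groups of values, where chance gives 11.8. At the low end these were Tnfrsf13c (0.881) and Slamf8 (0.848) in KO pH 6.7 replicate 3, Ferd3l in WT pH 6.7 replicate 3 (0.968) and WT pH 7.7 replicate 4 (0.898), Kif5c in KO pH 7.7 replicate 2 (0.86), Prss48 in KO pH 6.7 replicate 2 (0.886), Cylc2 (0.845) and Fhdc1 (0.849) in WT pH 6.7 replicate 4, and Fcrl1 in WT pH 7.7 replicate 1 (0.838). At the high end they were Lss in KO pH 7.7 replicate 4 (0.877), Matk (0.869) and Gper1 (0.895) in KO pH 6.7 replicate 4, Ntrk2 in WT pH 7.7 replicate 1 (0.883) and Nox3 in WT pH 6.7 replicate 2 (0.844).

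Of 11574 tested probe sets without a single gene symbol, which no comparison of genes used, 79 passed in the WT pH response, 316 in the KO response, 62 in the interaction, 3 between KO and WT at pH 7.7 and 17 at pH 6.7.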

How the results depend on the processing

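The fits that leave out an array together with averaging were chosen after seeing the data; the other alternatives were planned. The cause of the differences was not tested, except where fewer arrays, a stricter threshold or other probe sets make up the alternative. With all probe sets averaged, the counts were 743 (WT response), 1188 (KO response), 11 (interaction) and 4 (KO minus WT at pH 6.7), the correlation of the responses 0.326 and the list calls over the 5 comparisons 44 in place of 25, and 5 named values reversed: Cdh2 (−0.37), Rhob (0.15) and Ccnb2 (−0.34) in the KO response, Acvr1 (0.014) in the interaction and Itih5 (−0.03) in KO minus WT at pH 6.7. Without WT pH 7.7 replicate 2 as well, the counts were 585, 1449, 3 and 3 and the correlation 0.303. With every probe set tested by itself they were 313, 910, 18, 1 (KO minus WT at pH 7.7) and 7. An intensity trend with robust variances gave 311 in WT and 17 in KO minus WT at pH 7.7, where the stricter filter gave 3. Array weights gave 969 in KO and 116 in KO minus WT at pH 6.7. Fitting only the compared groups gave 22, 265 and 0 (WT, KO, KO minus WT at pH 6.7). Adjusted p under 0.01 left 41, 86, 6 and 3, and a change of at least 2-fold left 104 and 292 in WT and KO. Over genes past the threshold in at least 1 response the correlation was 0.16. With an estimated correlation 0 list calls remained of 25 by camera.

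Without 1 array at a time the counts ran from 79 to 172 (WT), 232 to 727 (KO), 51 to 129 (interaction), 0 to 10 (KO minus WT at pH 7.7) and 12 to 74 (KO minus WT at pH 6.7), the correlation from 0.019 to 0.121 and the list calls from 17 to 29. Of the called genes that the naming rule took, 19 of 40 passed in all 16 such fits in WT, 18 of 50 in KO, 11 of 19 in the interaction and 3 of 17 in KO minus WT at pH 6.7. Centring the arrays ended 1, 7, 3 and 1 of these calls in the same order, and averaging all probe sets left 35, 24, 1 and 0.

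The replicate numbers did not pair the arrays: same-numbered arrays deviated from their group means with correlations between −0.085 and 0.066 (24 pairs), and 5 of 16 arrays correlated best with an array of their own number. Over all probe sets the range was wider, −0.25 to 0.225, and was −0.236 to 0.229 for arrays of different numbers. With the number as a block the counts were 125, 402, 44, 1 and 34 (WT, KO, interaction, KO minus WT at pH 7.7 and at pH 6.7), the correlation of the responses 0.061 and the list calls 27. The distance of a dim gene from background was not measured, and precision is set by the 4 arrays per group.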

Other observations

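The test of the genes near the Ogr1 locus was chosen only after the result was seen. In WT the response to pH 6.7 reached further genes of the lists. Selp, the P-selectin gene that large peritoneal macrophages express, rose by a log2 fold change of 1.91 ± 0.27 (adjusted p = 0.00342; 2.55 over all probe sets), as did Ltbp1 (0.80 ± 0.18), while 14 of the 16 markers of large peritoneal macrophages did not pass. Egr1, the early growth response gene, rose by 1.78 ± 0.27 (1 of 31 early genes), Gdf15, a stress cytokine gene, by 1.38 ± 0.17 (1 of 14 genes of the p53 list), Thbs1, a matrix glycoprotein gene, by 1.09 ± 0.18 (1 of 28 matrix genes) and the glutathione reductase gene Gsr by 0.60 ± 0.12 (1 of 20 NRF2 targets). Isg15 of the interferon list (1 of 26) fell by 1.19, Pfkp of glycolysis (1 of 17) by 0.82, Cd22 of the B cell list (1 of 14) by 0.74 and Rhob of the cytoskeleton list (1 of 40) by 0.61. With all probe sets averaged Isg15 (−0.35, adjusted p = 0.137), Pfkp (−0.49, 0.0744) and Cd22 (−0.23, 0.217) did not pass, and they were lost in 14, 12 and 12 of the 16 fits that left out 1 array. Isg15 also did not pass with centred arrays (0.052) or array weights (0.0804). With the replicate number as a block Cd22 (0.0908), Pfkp (0.0906), Ltbp1 (0.077) and Rhob (0.0539) did not pass. Ltbp1 was lost in 11 of those fits, and after another quantile normalization it had an adjusted p of 0.0713 and Gsr of 0.0764. No gene of 23 in the phagocytosis list or of 18 in that of matrix proteases passed in WT by limma, with 5 and 6 at an unadjusted p under 0.05.

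In KO, Gdf15 (1.67 ± 0.17, adjusted p = 0.000321) and Pmaip1 (1.11 ± 0.24) of the p53 list rose, with 0.84 and 0.48 over all probe sets, and 12 did not pass. Hilpda rose (1.51 ± 0.27), as 1 of 19 genes of low oxygen, with 0.79 and an adjusted p of 0.0573 over all probe sets. The matrix genes Col5a1 (−1.45 ± 0.33) and Fbln1 (−0.98 ± 0.23) and the mesothelial marker Msln (−0.91 ± 0.21) fell, with 26 of 28 and 12 of 13 genes of their lists not past the threshold, and Col5a1, Fbln1 and Msln did not pass over all probe sets (−0.22, −0.23 and −0.29). Single genes also fell in the lists of adhesion (Alcam, −0.79), cytoskeleton (Actn1, −0.80, and Rhob, −0.44), chemokines (Cxcl10, −1.04), glycolysis (Pfkp, −0.78), matrix proteases (Mmp12, −0.53), phagocytosis (Colec12, −0.64) and B cells (Cd22, −0.76). Over all probe sets Rhob turned to 0.15 (adjusted p = 0.67), and Cxcl10 (−0.16, 0.469), Pfkp (−0.34, 0.174), Mmp12 (−0.14, 0.42) and Colec12 (−0.32, 0.119) did not pass, while Alcam, Actn1 and Cd22 did. With centred arrays the adjusted p was 0.105 for Rhob, 0.108 for Mmp12, 0.0526 for Actn1, 0.0551 for Colec12, 0.0555 for Msln and 0.0508 for Fbln1, and Rhob and Mmp12 were lost in 13 and 12 of the 16 fits without 1 array. Ccnb2 of the cell cycle list rose (0.69), as 1 of 29, and had −0.34 over all probe sets. With the block Rhob (0.086), Mmp12 (0.0744), Actn1 (0.0707), Ccnb2 (0.07), Alcam (0.0641) and Pfkp (0.0586) did not pass, and after another quantile normalization Msln (0.0683), Mmp12 (0.0551), Cxcl10 (0.0546) and Rhob (0.0511) did not. Actn1 was lost in 8 of the fits without 1 array, and Alcam, Ccnb2 and Cxcl10 in 7 each. The pH response of Msln in KO was also below that in WT (difference −1.46 ± 0.30), with a change of 0.55 in WT that did not pass (adjusted p = 0.288), and Msln was lower in KO at pH 6.7 (−1.09 ± 0.21), by its brightest probe set. Both calls were lost over all probe sets (−0.30 and −0.23), with centred arrays (adjusted p = 0.0778 and 0.0622), after another quantile normalization (0.0847 and 0.0775), with an intensity trend (0.0694 and 0.0772), with the replicate number as a block (0.0787 and 0.0699) and in 15 and 11 of the 16 fits without 1 array.

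In 15 of the 41 lists no tested gene passed in any of the 5 comparisons by limma. These are the proton sensors, the vacuolar proton pump, autophagy, targets of NF-kB, antigen presentation by MHC class II, complement, respiratory chain, heat shock, and the markers of small peritoneal macrophages, T and NK cells, mast cells, neutrophils, eosinophils, dendritic cells and red blood cells. Of their 166 tested genes, 19 had an unadjusted p under 0.05 in the WT response, 25 in the KO response, 24 in the interaction, 11 in KO minus WT at pH 7.7 and 16 at pH 6.7. Of all 15770 genes, 2051, 3308, 2264, 1703 and 1765 did in the same order. The lists were picked for having no call, which leaves out the smallest p, so these shares near or below those of all genes decide nothing about the lists. Single lists differed. In the interaction 6 of 13 complement genes and 4 of 10 mast cell markers had an unadjusted p under 0.05, against 0 of 10 T and NK cell markers and 0 of 7 neutrophil markers.

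A hypothesis was that genes near the Ogr1 locus differ between KO and WT because DNA of the strain of the targeting cells could have been carried along with the mutation. Of 39 tested genes of that list, 0 passed between KO and WT at pH 7.7 or pH 6.7 by limma, with 4 and 7 at an unadjusted p under 0.05 (10.3% and 17.9%, against 10.8% and 11.2% of all genes). Adjusted over the list alone, 0 differed at pH 7.7, and 3 were higher and 1 lower at pH 6.7. For the genotype effect over both pH values, 2 of the 39 had an unadjusted p under 0.05, and 81.7% of 10000 random lists matched on mean intensity held as many. The hypothesis stays open, since variants in a few of these genes would not be seen in such counts.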
